A study of Sus scrofa with 40 samples.

How the data were processed

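Total RNA of 40 primary cultures of pig coronary endothelial cells was hybridised to Affymetrix porcine genome arrays, per the labels' protocols, with 1 array for native and 1 for regenerated cells in each of 20 pairs, counted as 20 animals. The deposited values are intensities on a linear scale, MAS5 signals per the submitters' processing notes, with the MAS5 version not given in the sources used here. Their 2% trimmed mean was 500.1 on every array, so each array had been scaled on its own. MAS5 combines the probes of a probe set on each array separately and leaves more spread at low signal than at high signal, so a small change of a dim probe set is hard to detect here, and no detection calls were used here. RNA quality was read from the 3'/5' signal ratios of the actin and GAPDH control probe sets, with a limit of 10. No column belonged to another sample.

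Groups and pairs come from the labels. The replicate numbers in the sample titles pair the native and regenerated arrays of each diet group, since the study's design text states that both came from each animal and were compared in pairs. As a check, the correlation of the deviations of the paired arrays from their group means was above 0.1 in 17 of 20 pairs, with a median of 0.51 against -0.05 for other pairs, and below 0 in 3 (control animals 4 and 5 and FO animal 6). Labels of 5 control animals have MA numbers and those of the other 15 animals name the artery. In 14 of these 15 pairs both labels carry the same animal number, and in FO pair 6 they name different animals. In the 5 MA pairs the native and regenerated labels carry 2 different, consecutive MA numbers, so these labels do not show that both arrays came from 1 animal, and 2 of the 5 are among the 3 pairs below 0. The pairing of these 5 rests on the replicate numbers and the design text, and fits with artery-named animals alone and with no replicate block do without it. The label style was treated as a possible batch that only control animals span. Animals are separate samples. Where regenerated and native cells were compared, p-values of single probe sets measure how the paired differences vary between animals, pooled over the 3 diets. In native cells they measure the spread between animals, also pooled over the diets. P-values of the exact tests measure the spread between the animals of the groups compared. Those of gene lists with a preset correlation, described below, compare genes with genes and assume that the genes hardly vary together. The estimated correlation between genes was 0.86 for the interferon list in control pairs.

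The values were taken as log2(signal + 16), and fold changes are on that scale, which understates changes of dim probe sets. The 124 Affymetrix control probe sets were left out of 24123, and probe sets whose mean log2 level over all arrays lay at or below the 25th percentile were left out, which left 17999 (74.6% of the table). Linear models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the data.table package, version 1.17.8. The regenerated effect in each diet was fitted on all 40 arrays with the animal as a fixed block, the differences between diets were contrasts in that fit, and native cells were compared on the 20 native arrays. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the probe sets of each of 7 comparisons, with a threshold of 0.05. These tests, the gene lists, the rule for named genes and all alternatives were chosen before the data were examined, except for those said below or in the closing parts to be chosen later. The written plan does not list the correlations between list shifts, the simulations and splits for shared controls, or the adjustment over 1 list alone.

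Gene names came from the authors' deposited tables, which list 12112 of the probe sets with titles, and from a RefSeq gene table of the pig and a table of gene names. A single symbol was found for 3153 probe sets (2621 symbols, 1150 of them provisional LOC names), 62 had several and 8897 listed probe sets had none. Titles in 1 deposited file were left out because they disagreed with those of the others. The genes named per comparison were the 10 largest rises and 10 largest falls among genes that passed, or, where fewer than 10 passed, all of these and the 5 smallest p-values, up to 4 members of each list with the smallest p, and a fixed set of vascular and lipid genes. Results for 2 of these genes are not reported here. Of 28 fixed lists of pathway genes and cell type markers, 22 had at least 5 measured genes and were tested with limma's camera at a preset correlation between genes of 0.01, over 2381 genes with the probe set of highest mean level each, and adjusted over the lists. Camera with an estimated correlation was an alternative. P-values of single genes were also adjusted over the members of 1 list alone. That does not correct for the number of lists or comparisons, so such calls are weaker than those over all probe sets. An exact test of each animal's list mean, by sign flips within pairs or by permutation of animals between diets, was added after seeing the data.

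The alternatives were quantile normalization, pseudocounts of 1 and 64, a filter at the 50th percentile or none, array quality weights, artery-named animals alone, the label style as a batch term, no replicate block, the animal as a random block, FO pair 6 left out, the mean over all probe sets of a gene, and the methods' t-test, paired within groups as the study's design text states. Each of the 20 animals was also left out in turn, as planned for probe set counts and added after seeing the data for gene lists. Fits without the 2 animals with degraded RNA, fits without the 3 pairs whose arrays correlated below 0, the exchange of native and regenerated arrays in each pair in turn and the mean effect over the 3 diets were added after seeing the data. Other splits of the samples were drawn up to 100 times per comparison, and correlations were tested with 100000 permutations.

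The fits were tested on simulated data with the means and spreads of the 17999 probe sets and 100 changed probe sets per fold size. For a log2 change of 1 the share recovered was 79% in control pairs, 69% in CHL and in FO pairs, 33% and 40% for the CHL and FO differences from control, and 54% and 60% for native CHL and native FO cells, and for a log2 change of 2 it was 90% to 99%. Between 3.53% and 10.3% of the calls were unchanged probe sets. Camera called a simulated list of 22 genes shifted by 0.5 and 0 other lists in each comparison with either correlation, but simulated genes did not vary together as real genes do.

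The authors also deposited 13 tables of fold changes, as ratios of at least 1 with a direction column, per the file headers, and 1 of them gives log2 fold changes, per the file headers. How probe sets were chosen for these tables is not given in the sources used here. Over the listed probe sets, 38 sets of folds in the authors' deposited tables had correlations from 0.815 to 0.993 with the fitted changes, and for 1 of them the 2 headings name opposite directions, so that the direction column was used. In the authors' deposited table of single control pairs, with 4165 probe sets, 8 of 8 pairs lay closest to the pair of the same number. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.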

Results

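Gene expression was measured in primary cultures of coronary endothelial cells, the cells that line the inside of the arteries of the heart, from 20 female farm pigs aged 4 months. Each animal gave 2 cultures per the study's design text, and the 20 pairs are counted as 20 animals. The labels of FO pair 6 name different animals, and the labels of 5 control pairs do not show a shared animal. Native cells came from the left circumflex artery, and regenerated cells came from a part of the left anterior descending artery whose lining had been removed earlier and had grown back. The animals were 8 controls, 6 animals fed high cholesterol (CHL) and 6 animals of a group rich in polyunsaturated fatty acids, which the study's title describes as rich in fish oil (FO). Cultures were grown for 10 days without passage, and each was hybridised to 1 Affymetrix porcine array, which made 40 arrays. The 2% trimmed mean signal was 500.1 on every array, and the median signal ran from 75.8 to 121. No 2 arrays were identical, and correlations between arrays ran from 0.827 to 0.984. The precision is limited by the number of arrays in each group.

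On 38 arrays the 3'/5' signal ratio of the control transcripts, which is high where RNA is degraded, lay between 1.33 and 6.89 for actin and between 0.935 and 1.82 for GAPDH. The regenerated array of control animal 6 had ratios of 264 and 1005. That of FO animal 3 had 422 and 59.9. Native and regenerated cells always came from different arteries, so every difference between them below is also a difference between the arteries. Of the 23999 gene probe sets, 3153 could be given 1 gene symbol, so most changes lie in probe sets without a name here.

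The first question was which genes differ between the regenerated and native cells of a control pair. In the 8 control pairs, regenerated cells had higher ACTA2, the alpha actin of smooth muscle, and higher GPC4, a cell surface proteoglycan. They had lower CALCB, which encodes a vasodilator peptide of the calcitonin gene family, and lower ADAM17, a protease that sheds membrane proteins. They also had lower OLR1, the endothelial receptor for oxidised low density lipoprotein. Of 17999 probe sets tested, 18 rose and 34 fell after Benjamini-Hochberg adjustment in limma, and 4890 had an unadjusted p under 0.05 where 899.95 were expected by chance. After quantile normalization 36 rose and 28 fell. With 1 probe set per symbol, the one of highest mean level, 12 of 2381 genes changed, 4 upward and 8 downward. CANX changed only by another of its probe sets (-0.63, adjusted p = 0.0371).

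ACTA2 rose 12.3-fold, from a mean log2 level of 8.20 ± 2.53 to 11.82 ± 2.39 (SD, n = 8), with a log2 change of 3.62 (SE 0.77, adjusted p = 0.0487), and was higher in 6 of 8 pairs. GPC4, at 8.26 ± 0.99 in native cells (SD, n = 8), rose 3.33-fold, with a log2 change of 1.74 (SE 0.37, adjusted p = 0.0487), in 8 of 8 pairs. A furry-like gene, LOC100155799, rose by 1.43 on the log2 scale (SE 0.29, adjusted p = 0.0359), and an amino acid transporter-like gene, LOC100154364, rose by 1.20 (SE 0.26, adjusted p = 0.0487), each in 7 of 8 pairs. CALCB fell in 8 of 8 pairs, from 9.74 ± 1.17 to 8.22 ± 1.03 (SD, n = 8), a log2 change of -1.51 (SE 0.24, adjusted p = 0.00859). ADAM17 also fell in 8 of 8 pairs, by 1.23 on the log2 scale (SE 0.20, adjusted p = 0.0109). OLR1 fell from 7.98 ± 2.35 to 5.58 ± 0.71 (SD, n = 8), a log2 change of -2.40 (SE 0.52, adjusted p = 0.0492), in 7 of 8 pairs. Smaller falls were seen in a semaphorin-4D-like gene, LOC100152598 (-0.96, adjusted p = 0.0371), and in KITLG, the ligand of the receptor KIT (-0.96, adjusted p = 0.0359). The last to fall were SON, a protein of splicing speckles (-0.91, adjusted p = 0.0427), and a KIAA0157-like gene, LOC100158023 (-0.52, adjusted p = 0.0359). Each of these 4 was lower in at least 7 of 8 pairs.

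**Figure D1:**
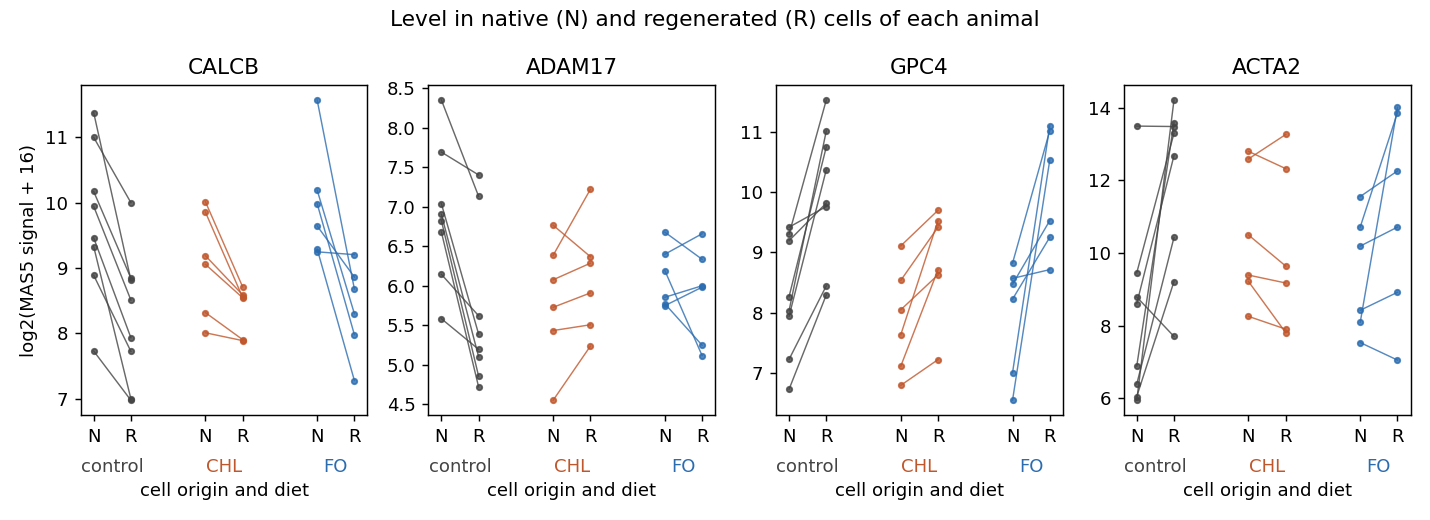
Level of CALCB, ADAM17, GPC4 and ACTA2 in native (N) and regenerated (R) cells, as log2 of the MAS5 signal plus 16 on each vertical axis, with 1 line per animal and the diets side by side (8 control, 6 CHL and 6 FO pairs). CALCB is lower in regenerated cells in 20 of 20 pairs and GPC4 is higher in 20 of 20, while ADAM17 is lower in 8 of 8 control pairs with a mean change of 0.26 in CHL pairs.

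The gene lists chosen before the data were examined were then tested with camera, which asks whether a list's genes shift relative to other genes. Of 22 lists, 3 passed in control animals, all with a preset correlation between genes and none with an estimated one. The interferon response list fell in regenerated cells, with a median log2 change of -1.13 over 22 measured genes (adjusted p = 3.91e-06, and adjusted p = 0.565 with an estimated correlation). All 22 genes were lower, 20 of them fell when adjusted over the list alone, and 0 did over all probe sets by limma. MX2, an antiviral GTPase, had a log2 change of -1.83 (SE 0.45), IRF7, a transcription factor of the interferon response, -1.81 (SE 0.51) and PSMB8, a subunit of the immunoproteasome, -1.54 (SE 0.40). The list mean was lower in 5 of 8 pairs, with an exact sign-flip p of 0.0625 (two-sided). The 2 largest falls were in control animals 4 (-2.54) and 5 (-3.31), the control pairs whose arrays correlated below 0, and these also had the largest smooth muscle rises (1.71 and 2.60).

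The smooth muscle list rose, with a median log2 change of 0.79 over 12 genes (adjusted p = 4.2e-06, and adjusted p = 0.565 with an estimated correlation). All 12 were higher, 8 rose when adjusted over the list alone, and ACTA2 also did over all probe sets. MYL9, a light chain of smooth muscle myosin, had a log2 change of 1.40 (SE 0.32), TAGLN, an actin-binding protein of smooth muscle, 1.38 (SE 0.33) and CALD1, which regulates contraction, 0.77 (SE 0.23). The list mean was higher in 7 of 8 pairs (exact sign-flip p = 0.0156, two-sided). Its level went from 8.29 ± 0.90 in native cells to 9.34 ± 0.80 in regenerated cells (SD, n = 8). In the same pairs the level of 14 endothelial genes went from 9.61 ± 0.23 to 9.52 ± 0.26 (SD, n = 8), a list that did not pass (adjusted p = 0.869).

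The inflammatory adhesion and chemokine list fell, with a median log2 change of -0.91 over 21 genes (adjusted p = 0.0298, and adjusted p = 0.844 with an estimated correlation). Over the list alone 11 of its genes fell and 1 rose, and 0 passed over all probe sets by limma. SELE, an adhesion receptor for leukocytes, had a log2 change of -2.14 (SE 0.60), the cytokine IL6 -2.99 (SE 0.94) and NFKBIA, an inhibitor of NF-kappaB, -1.02 (SE 0.30). The inflammatory list mean was lower in 6 of 8 pairs (exact sign-flip p = 0.0703).

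The other lists did not pass, but some of their genes did when adjusted over the list alone. In the list of proteases and matrix remodelling 9 of 21 genes rose and 3 fell (list adjusted p = 0.117). Those that rose include MMP7, a matrix protease, at 1.84 (SE 0.41), LOXL1, which crosslinks elastin, at 1.08 (SE 0.29) and TIMP2, a protease inhibitor, at 0.65 (SE 0.21). The adipocyte list had 3 of 5 genes up (list adjusted p = 0.114). They were PPARG, a nuclear receptor of lipid storage, at 1.30 (SE 0.29), the fatty acid carrier FABP4 at 1.55 (SE 0.44) and LPL, a lipase, at 0.57 (SE 0.18). The fatty acid synthesis list had 4 genes down and 1 up of 9 (list adjusted p = 0.377). FASN, the fatty acid synthase, was lower in 8 of 8 pairs at -1.03 (SE 0.30), and the desaturase FADS2 was at -0.56 (SE 0.16). Its list mean was lower in 8 of 8 pairs (exact sign-flip p = 0.00781, adjusted over the lists 0.0858). The fibroblast list had 4 genes up and 4 down of 10, among them FAP at 1.65 (SE 0.57) and POSTN at -2.10 (SE 0.66). For the endothelial-to-mesenchymal transition and TGF-beta list the counts were 5 up and 3 down of 16 (list adjusted p = 0.188). TWIST1, a transcription factor, was at 1.22 (SE 0.41) and the receptor TGFBR2 at -2.40 (SE 0.65). Of 13 cholesterol transport genes 4 rose and 3 fell, and their median (0.16) and mean (-0.19) differed in sign. Of the genes fixed for every comparison, the nitric oxide synthase NOS3 had a log2 change of 0.05 (adjusted p = 0.883), the endothelin gene EDN1 0.10 (0.804) and the adhesion molecule VCAM1 -0.13 (0.536). The thromboxane synthase TBXAS1 was at 0.59 (adjusted p = 0.193) and the cyclooxygenase PTGS1 at -1.56 (0.0676).

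These control results depended on the animals used. Leaving out 1 animal gave between 9 probe sets, without control animal 5, and 2398, without control animal 8. Without the 2 animals whose regenerated RNA was degraded 1 rose and 15 fell. Control animals carry labels of 2 styles. The mean shift in the 5 animals with MA numbers and the 3 with artery names was 1.29 and 0.65 for smooth muscle, -1.56 and -0.60 for interferon response and -1.15 and -0.71 for the inflammatory list. The inflammatory call was lost without control animal 4 or 5 (highest adjusted p = 0.114), without the animals with degraded RNA (adjusted p = 0.0593) and with artery-named animals alone (adjusted p = 0.0884). With artery-named animals alone 0 probe sets passed by limma, so that none of the 12 genes kept its call, and 803 had an unadjusted p under 0.05. Without the 3 pairs whose arrays correlated below 0 (control animals 4 and 5 and FO animal 6), 6 probe sets passed and none of the 12 genes. The interferon and smooth muscle lists then passed with smaller medians (-0.61 and 0.48, adjusted p = 1.48e-05 and 1.15e-05), and the inflammatory list did not (-0.50, adjusted p = 0.189). The log2 change of OLR1 ran from -2.89 to -0.54 over the alternative fits.

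**Figure D2:**
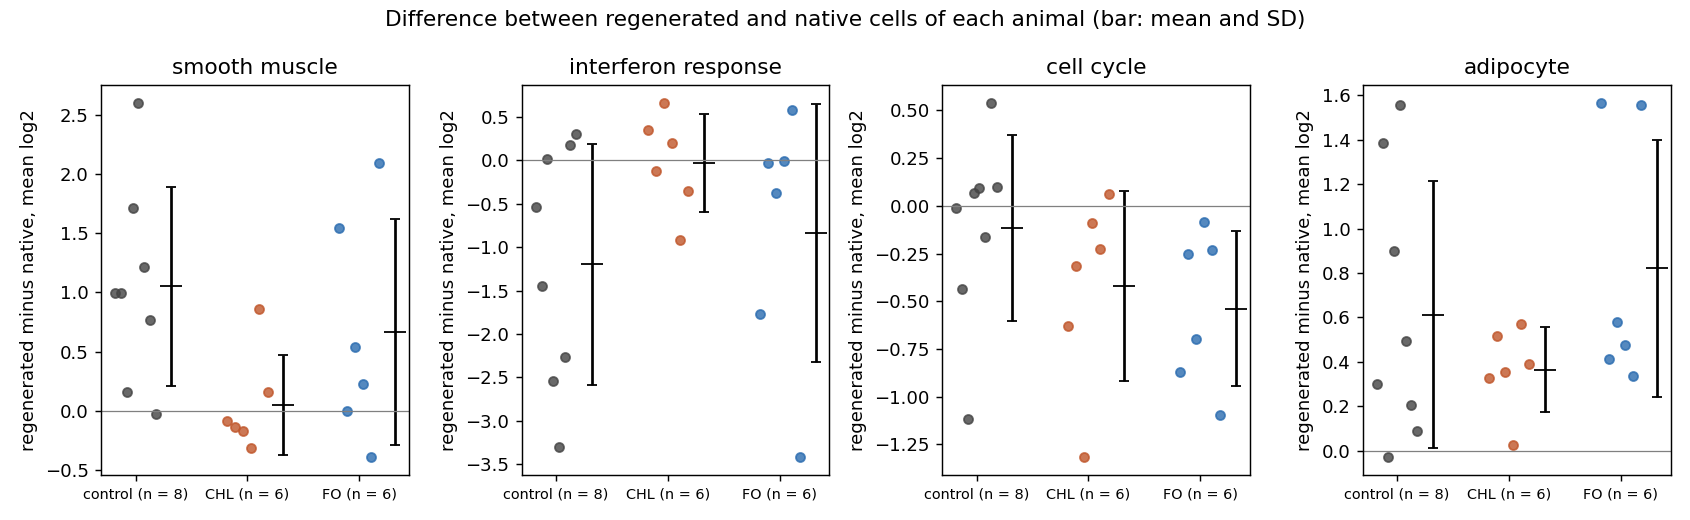
Mean log2 level in regenerated minus native cells for the smooth muscle, interferon response, cell cycle and adipocyte lists, with 1 point per animal and a bar at the mean with its SD (8 control, 6 CHL and 6 FO animals). The mean smooth muscle difference is 1.05 in control pairs with 7 of 8 above 0, the mean interferon difference is -1.20 with 5 of 8 below 0, and the adipocyte difference is above 0 in 6 of 6 FO pairs.

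The same comparison in CHL animals asked which genes differ between regenerated and native cells under a high cholesterol diet. No gene with a symbol passed. By limma 1 probe set fell, 0 rose, and 1145 had an unadjusted p under 0.05. The probe set is titled only as a transcribed locus in the authors' deposited tables, and it is singled out after its values were seen. It fell 12.4-fold in 6 of 6 CHL pairs (log2 change -3.63, SE 0.48, adjusted p = 0.00324) and also fell in control (-3.53, SE 0.41, adjusted p = 0.000132) and FO pairs (-3.52, SE 0.48, adjusted p = 0.00261). The genes with the smallest p did not pass. They were a gene with leucine-rich repeats, LOC100156782, at -1.11 (SE 0.21, adjusted p = 0.101), coagulation factor F5 at -1.18 (SE 0.24, adjusted p = 0.21), the heme carrier HPX at 0.84 (SE 0.21), P311 at -1.24 (SE 0.31) and a WD repeat gene, LOC100154588, at -0.57, the last 3 with an adjusted p of 0.327.

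In CHL pairs 2 of 22 lists passed, and neither did with an estimated correlation. The cell cycle list fell, with a median log2 change of -0.45 over 22 genes (adjusted p = 5.77e-07, and adjusted p = 0.66 with an estimated correlation). Of its genes 20 were lower and 0 passed by limma over the list alone. KIF20A, a kinesin of cell division, was at -0.78 (SE 0.26), BIRC5, which encodes survivin, at -0.83 (SE 0.30) and cyclin CCNB1 at -0.78 (SE 0.35). Its level went from 9.48 ± 0.27 to 9.06 ± 0.42 (SD, n = 6) and was lower in 5 of 6 pairs (exact sign-flip p = 0.0625), by 1.32 in CHL animal 3. The median ran from -0.55 to -0.22 with 1 animal left out. The oxidative phosphorylation list fell by a median of 0.15 over 25 genes (adjusted p = 0.0039, and adjusted p = 0.899 with an estimated correlation). In it 22 genes were lower, and NDUFV1, a subunit of complex I, was at -0.22 (SE 0.13). This call was lost without CHL animal 4 (adjusted p = 0.623). The smooth muscle and interferon lists had medians of 0.07 (adjusted p = 0.851) and -0.06 (adjusted p = 0.823). The adipocyte and coagulation lists were higher in 6 of 6 pairs (exact sign-flip p = 0.0312 for each) without passing camera (adjusted p = 0.313 for each). Over the list alone F5 and POSTN (-2.69, SE 0.77) fell. NOS3 had a log2 change of -0.01, FABP4 0.63, MMP7 0.58, PTGS1 -0.01, TBXAS1 -0.01, EDN1 -0.19 and VCAM1 0.07, with adjusted p between 0.888 and 0.999.

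In FO animals the comparison asked the same in the fish oil group. CALCB fell in 6 of 6 pairs, from 9.99 ± 0.86 to 8.38 ± 0.69 (SD, n = 6), a log2 change of -1.61 (SE 0.28, adjusted p = 0.0361). It was the only gene with a symbol among 7 probe sets that fell by limma, while 0 rose and 1558 had an unadjusted p under 0.05. A probe set that the authors' deposited table titles as a zinc finger protein fell by 1.80 on the log2 scale (SE 0.24, adjusted p = 0.00261) and also fell in control pairs (-1.83, SE 0.21, adjusted p = 9.73e-05), and one titled butyrylcholinesterase fell by 1.91 (SE 0.30, adjusted p = 0.0149). These 2 were named after their values were seen. The next genes did not pass: GPC4 at 2.09 (SE 0.42, adjusted p = 0.119), PPARG at 1.62 (SE 0.33, adjusted p = 0.119), LOC100156782 at -1.01 (adjusted p = 0.119) and POSTN at -3.58 (SE 0.77, adjusted p = 0.16). GPC4 and PPARG were higher in 6 of 6 pairs, and POSTN, a matrix protein, was lower in 6 of 6.

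Of 22 lists 6 passed in FO pairs, 3 higher and 3 lower, and 0 did with an estimated correlation. The cell cycle list fell (median -0.59 over 22 genes, adjusted p = 1.16e-05, and adjusted p = 0.555 with an estimated correlation). It was lower in 6 of 6 pairs (exact sign-flip p = 0.0312, the smallest that 6 pairs allow), and over the list alone the mitotic kinase PLK1 fell (-0.95, SE 0.27). The interferon list fell (median -0.82 over 22 genes, adjusted p = 1.29e-05, and adjusted p = 0.739 with an estimated correlation). All 22 genes were lower, with MX1 at -1.02 (SE 0.43) and RSAD2, an antiviral enzyme, at -1.49 (SE 0.67). The call was lost without FO animal 6 (adjusted p = 0.199), and 5 of 6 pairs were lower (exact sign-flip p = 0.281). The smooth muscle list rose (median 0.66 over 12 genes, adjusted p = 0.000522, and adjusted p = 0.555 with an estimated correlation). It was higher in 4 of 6 pairs (exact sign-flip p = 0.188), and over the list alone PLN, which controls the calcium pump of muscle, rose (0.98, SE 0.23). The adipocyte list rose (median 0.76 over 5 genes, adjusted p = 0.00943, and adjusted p = 0.307 with an estimated correlation). It was higher in 6 of 6 pairs (exact sign-flip p = 0.0312), with PPARG and FABP4 (1.67, SE 0.51) up over the list alone. Over all probe sets these 2 genes had an adjusted p of 0.119 and 0.379 by limma. The list of proteases and matrix remodelling rose (median 0.17, adjusted p = 0.00943, and adjusted p = 0.555 with an estimated correlation). Of its genes 17 of 21 were higher, with MMP7 at 1.53 (SE 0.48), and the list mean was higher in 5 of 6 pairs (exact sign-flip p = 0.219). The ribosomal protein list fell (median -0.12, adjusted p = 0.0107, and adjusted p = 0.83 with an estimated correlation). There 34 of 38 genes were lower, and the list mean was lower in 5 of 6 pairs (exact sign-flip p = 0.469). Over other lists alone OLR1 (-2.54, SE 0.60), KITLG (-0.87, SE 0.22) and TFPI, an inhibitor of coagulation (-1.08, SE 0.39), fell, and the chemokine CXCL12 (2.01, SE 0.56) and TBXAS1 (1.32, SE 0.34) rose. None of these genes passed over all probe sets by limma, where the adjusted p of TBXAS1 was 0.231. NOS3 was at -0.20, EDN1 at -0.48, VCAM1 at -0.38 and PTGS1 at -0.68, with adjusted p between 0.507 and 0.753.

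In FO pairs the adipocyte call was lost without FO animal 6 (adjusted p = 0.0548), the protease call without FO animal 1 or 6 (highest adjusted p = 0.0948) and the ribosomal call without FO animal 1, 3 or 6 (highest adjusted p = 0.304). The smooth muscle median ran from 0.37 to 0.86 with 1 animal left out, and the shift was largest in FO animals 1 (1.54) and 6 (2.09). The labels of the native and regenerated arrays of FO pair 6 name different animals, and without that pair 2 probe sets passed and CALCB did not. The CALCB call in FO pairs was lost in 9 of 13 alternative settings and in 9 of 20 fits without 1 animal.

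Across the 3 diets, the changes of control and FO pairs had a correlation of 0.635 over probe sets, which are not independent replicates. Of the 7 probe sets called in FO, 6 were also called in control in the same direction, where 0.0132 were expected of independent sets. These sets are not independent, since 1 fit gave both and shares each probe set's spread over the diets. The expected number can therefore understate what chance gives. For control and CHL pairs the correlation was 0.00577, and for CHL and FO pairs 0.400.

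The next question was whether the change from native to regenerated cells differed between CHL and control animals. No probe set passed by limma (0 of 17999, smallest adjusted p = 0.287, with 2625 at an unadjusted p under 0.05, 0 by an adjusted test of each probe set on its own, and 1 with the animal as a random block). The smallest p among named genes was for a TRIM-like gene, LOC100156139, whose change was 1.93 higher in CHL (SE 0.35, adjusted p = 0.287). For ADAM17 the change was -1.23 ± 0.73 in control pairs and 0.26 ± 0.44 in CHL pairs (SD), a difference of 1.49 (SE 0.31, adjusted p = 0.316). ADAM17 was above the control mean in 6 of 6 CHL animals and passed over its list alone. The LIF receptor gene LOC397451 (1.16), AAR2 (0.79) and a chromatin remodelling-like gene, LOC100157302 (-1.06), had an adjusted p of 0.316 each.

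The change of 5 of 22 lists differed between CHL and control, and of 0 with an estimated correlation, where the adjusted p was 0.652 for each. Below, higher and lower in CHL refer to this change. The interferon list was 1.13 higher in CHL by its median (adjusted p = 0.00017, and adjusted p = 0.652 with an estimated correlation). In this list 22 of 22 genes were higher, with MX2 at 1.63 (SE 0.68) and IRF7 at 1.74 (SE 0.78), and 6 of 6 CHL animals were above the control mean (exact permutation p = 0.0793). The smooth muscle list was lower in CHL (median -0.81, adjusted p = 0.00017, and adjusted p = 0.652 with an estimated correlation). Here 12 of 12 genes were lower, ACTA2 was at -4.06 (SE 1.17) and past the threshold over the list alone, and 6 of 6 CHL animals were below the control mean (exact permutation p = 0.0183). The mean smooth muscle level was 9.09 in CHL and 8.29 in control native cells, and 9.14 and 9.34 in regenerated cells. The inflammatory list was higher (median 0.80, adjusted p = 0.00636, and adjusted p = 0.652 with an estimated correlation). Of its genes 20 of 21 were higher, among them the adhesion receptor SELP at 1.69 (SE 0.58) and the cytokine IL1A at 2.38 (SE 0.96) (exact permutation p = 0.105). The cell cycle list was lower (median -0.51, adjusted p = 0.00387, and adjusted p = 0.652 with an estimated correlation, exact permutation p = 0.279), with TYMS, which makes thymidylate, at -0.73 (SE 0.27). The oxidative phosphorylation list was lower (median -0.16, adjusted p = 0.0288, and adjusted p = 0.652 with an estimated correlation, exact permutation p = 0.412). The fatty acid synthesis list did not pass camera (adjusted p = 0.261), but 6 of 6 CHL animals were above the control mean (exact permutation p = 0.00266, adjusted over the lists 0.0585). FASN (1.37, SE 0.45), GPAM (0.86, SE 0.26) and LPIN1 (0.69, SE 0.22) were higher over the list alone. Over other lists alone FLT1, a receptor for VEGF (1.44, SE 0.41), VEGFA (1.03, SE 0.32), the urokinase gene PLAU (1.67, SE 0.53) and COL1A2 (0.90, SE 0.23) were higher in CHL and the proteoglycan BGN was lower (-1.83, SE 0.48). PTGS1 was at 1.55, MMP7 at -1.25, FABP4 at -0.92 and NOS3 at -0.06, and none passed.

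Against the 3 artery-named controls alone the mean differences were 0.56 for interferon, where camera no longer passed (adjusted p = 0.117), -0.60 for smooth muscle, 0.92 for the inflammatory list and -0.58 for cell cycle. Without CHL animal 3 the cell cycle (adjusted p = 0.104) and inflammatory (adjusted p = 0.103) calls were lost, and the oxidative phosphorylation call was lost without CHL animal 4, control animal 3 or control animal 8 (highest adjusted p = 0.405).

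The change in FO animals was set against that of control animals in the same way. No probe set passed by limma (0 of 17999, smallest adjusted p = 0.909, with 756 at an unadjusted p under 0.05 and 0 by an adjusted test of each probe set on its own). In FO 2 of 22 lists were lower. One was cell cycle (median -0.56 over 22 genes, adjusted p = 4.85e-06, and adjusted p = 0.662 with an estimated correlation). The other was ribosomal proteins (median -0.09 over 38 genes, adjusted p = 0.0223, and adjusted p = 0.954 with an estimated correlation). The ribosomal median was 0.02 after quantile normalization. For cell cycle 18 of 22 genes were lower, with TYMS at -0.69 (SE 0.27), CCNB1 at -1.07 (SE 0.46) and BUB1B, a checkpoint kinase, at -1.08 (SE 0.53). In all, 5 of 6 FO animals were below the control mean (exact permutation p = 0.114). Against the 3 artery-named controls the mean cell cycle difference was -0.70. Neither list passed camera without the 3 pairs whose arrays correlated below 0. The ribosomal list had 29 of 38 genes lower (exact permutation p = 0.533). The smallest p values among genes, all with an adjusted p of 0.909, were for ADAM17 (1.01, SE 0.31) and MARCH6 (-0.87). The mean ADAM17 change was -0.22 in FO and -1.23 in control pairs, with 6 of 6 FO animals above the control mean change. These 2 genes were followed by RAD54L, a DNA repair gene (-0.91), LOC100158023 (0.47) and the growth factor FGF2 (1.11). FASN was at 1.35 (SE 0.45), and the fatty acid synthesis list gave an exact permutation p of 0.00966 without passing camera.

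The differences of native CHL and native FO cells from native control cells, given further below, share the control animals. Their correlation over probe sets was 0.786, against 0.430 in simulations with no effect, and their covariance was 0.104 against 0.0366. The simulations drew each probe set independently, which real probe sets are not. With the controls split between the 2 differences the correlation averaged 0.402 and ran from 0.0121 to 0.619 over 70 splits. The simulated value is for shared controls and does not apply to these splits. Both parts of every split held controls with MA numbers, while CHL and FO animals all have artery names. The label style was therefore not told apart from the diets here.

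**Figure D3:**
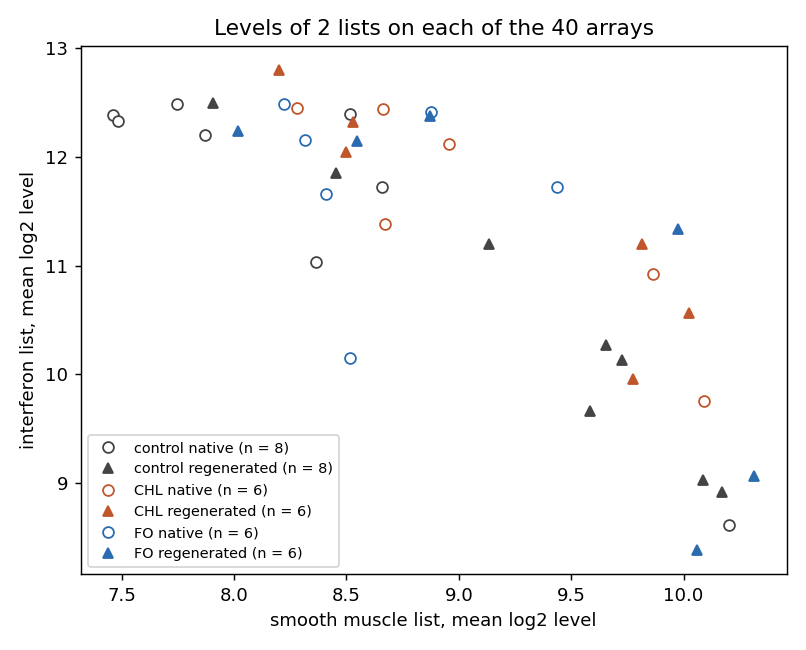
Mean log2 level of the interferon response list against that of the smooth muscle list on each of the 40 arrays, with filled triangles for regenerated and open circles for native cells, coloured by diet. Arrays with higher smooth muscle levels have lower interferon levels, and control native array 8 lies at 10.20 for smooth muscle and 8.62 for interferon, apart from the other control native arrays.

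Across the 20 animals the regenerated minus native shift of the interferon list moved against that of the smooth muscle list, with Pearson's r = -0.94 and Spearman's rho = -0.91 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give, adjusted to 6e-05 over 6 relations). Without the 2 animals farthest from the median r was -0.90, and within control, CHL and FO animals it was -0.91, -0.86 and -0.98. In the 15 animals with artery names r was -0.92. The inflammatory shift also moved against the smooth muscle shift (r = -0.77, rho = -0.68, permutation p = 3e-05 and 0.00135, adjusted p = 9e-05 and 0.00405, r = -0.63 without the 2 farthest, -0.93, -0.62 and -0.63 within the diets and -0.64 with artery names). The fibroblast shift moved with it (r = 0.70, rho = 0.57, permutation p = 0.00072 and 0.0102, adjusted p = 0.00144 and 0.0204, r = 0.48 without the 2 farthest, 0.89, 0.25 and 0.60 within the diets and 0.52 with artery names). The macrophage shift moved against it (r = -0.50, rho = -0.53, permutation p = 0.0265 and 0.0189, adjusted p = 0.0398 and 0.0284, r = -0.45 without the 2 farthest, -0.50, -0.56 and -0.57 within the diets and -0.31 with artery names). For the endothelial shift r was -0.37 and rho -0.38 (permutation p = 0.105 and 0.0984, r = -0.22 without the 2 farthest, -0.52, 0.49 and -0.41 within the diets and -0.37 with artery names). For the cell cycle shift r was 0.05 and rho 0.14 (permutation p = 0.82 and 0.547, r = 0.15 without the 2 farthest, 0.32, 0.28 and -0.91 within the diets and -0.27 with artery names). Both changed sign between diets. The 6 relations are not listed in the written plan, and all use the smooth muscle list, which had passed camera in these same data.

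Native cells were then compared between diets, which asks whether diet was tied to expression in vessels that had not been denuded. The same native arrays enter the CHL and FO differences in change above with the opposite sign, so these results are not independent of those. In native CHL cells against native control cells, genes of cell division were higher, among them UBE2C, a ubiquitin carrier of mitosis, at 0.92 (SE 0.23), BIRC5 at 1.37 (SE 0.37), CCNB1 at 1.34 (SE 0.41) and STMN1, a microtubule regulator, at 0.67 (SE 0.23), each above the control mean in 6 of 6 CHL animals. Of 22 cell cycle genes 10 rose when adjusted over the list alone and 0 over all probe sets by limma. The list rose by a median of 0.64 (adjusted p = 3.18e-07, and adjusted p = 0.667 with an estimated correlation), from a level of 8.88 ± 0.64 (SD, n = 8) to 9.48 ± 0.27 (SD, n = 6), with an exact permutation p of 0.0556. The 3 artery-named controls were at 8.40 and the 5 others at 9.18, so that the difference was 1.08 against the former and smaller against the latter. These 5 were at 9.47, 9.86, 9.31, 8.82 and 8.42, and CHL animals ran from 9.14 to 9.77.

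By limma 2 probe sets fell in native CHL cells and 0 rose, with 2693 at an unadjusted p under 0.05. Neither has a gene name in the authors' deposited tables. One was at -1.26 (SE 0.19, adjusted p = 0.0208), below the control mean in 6 of 6 animals, and the other at -1.84 (SE 0.29, adjusted p = 0.0208). They are given after their values were seen. By limma 0 passed with artery-named controls alone, with 1427 at an unadjusted p under 0.05, or with any 1 of the 6 CHL animals left out, and 566 passed with array quality weights and 232 without control animal 8. Named genes that did not pass, all with an adjusted p of 0.0944, were FLT1 at -1.25 (SE 0.26), the thyroid hormone receptor THRA at 0.95 (SE 0.18), AAR2 at -0.997 (SE 0.21), an RNF185-like gene, LOC100157569, at -0.85 (SE 0.16) and a replication factor C-like gene, LOC100156440, at 0.89 (SE 0.17).

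**Figure D4:**
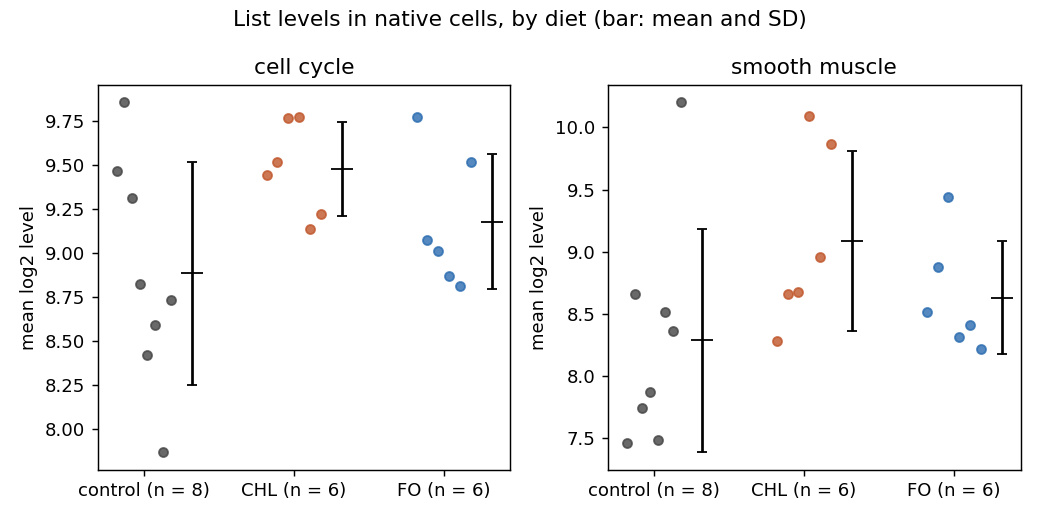
Mean log2 level of the cell cycle and smooth muscle lists in native cells, 1 point per animal, with bars at the mean with its SD for control (8), CHL (6) and FO (6) animals. Cell cycle levels average 8.88 in control and 9.48 in CHL animals, and smooth muscle levels average 8.29 and 9.09, with 1 control animal at 10.20.

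Besides cell cycle, 4 of the 22 lists passed in native CHL cells, and 0 with an estimated correlation. The smooth muscle list was higher (median 0.82 over 12 genes, adjusted p = 0.000407, and adjusted p = 0.667 with an estimated correlation, exact permutation p = 0.103). All 12 genes were higher, with DES, a muscle filament, at 0.86 (SE 0.27) and the tropomyosin TPM2 at 1.08 (SE 0.39). Against the 3 artery-named controls its mean difference was 0.06 and it did not pass (adjusted p = 0.914). The cholesterol synthesis list was higher (median 0.14, adjusted p = 0.027, and adjusted p = 0.667 with an estimated correlation, exact permutation p = 0.0233). In it 9 of 11 genes were higher, with the kinase MVK at 0.44 (SE 0.15) and the isomerase EBP at 0.43 (SE 0.15), and a difference of 0.22 against artery-named controls (adjusted p = 0.342). The ribosomal list was higher (median 0.14, adjusted p = 0.027, and adjusted p = 0.815 with an estimated correlation, exact permutation p = 0.43). There 32 of 38 genes were higher, with a difference of 0.09 against artery-named controls (adjusted p = 0.414). The inflammatory list was lower (median -0.84, adjusted p = 0.027, and adjusted p = 0.779 with an estimated correlation, exact permutation p = 0.114). Of its genes 15 of 21 were lower, IL18, a cytokine, was lower over the list alone at -2.01 (SE 0.47), and the list had a difference of -0.46 against artery-named controls (adjusted p = 0.57). Over other lists alone FLT1, FASN (-1.26, SE 0.31), GPAM (-0.64, SE 0.19), CPT1B, which carries fatty acids into mitochondria (-0.69, SE 0.21), and PDGFRA (-0.95, SE 0.30) were lower. LYZ, the lysozyme of macrophages (2.50, SE 0.59), and the fatty acid carrier FABP5 (1.63, SE 0.52) were higher. The cholesterol synthesis, inflammatory and ribosomal calls were each lost without some animals, 4, 7 and 5 of 20 in turn (highest adjusted p = 0.13, 0.147 and 0.477). PTGS1 was at -1.09, EDN1 at 0.22, VCAM1 at 0.11, NOS3 at 0.01, FABP4 at 0.43, MMP7 at 0.15 and TBXAS1 at 0.21, and none passed.

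In native FO cells against native control cells no probe set passed by limma (0 of 17999, smallest adjusted p = 0.103, with 1636 at an unadjusted p under 0.05, 0 by an adjusted test of each probe set on its own, and 84 with array quality weights). FLT1 was at -1.04 (SE 0.26, adjusted p = 0.2) and FASN at -1.24 (SE 0.31, adjusted p = 0.222), each below the control mean in 6 of 6 animals and lower over its list alone. A pecanex-like gene, LOC100154536, was at -1.93 (SE 0.45) and a transcription initiation factor-like gene, LOC100154605, at 0.93, each with an adjusted p of 0.188, and a GMP reductase-like gene, LOC100154068, was at 0.88 (adjusted p = 0.219). Of 22 lists 2 were higher. One was cell cycle (median 0.32 over 22 genes, adjusted p = 0.00226, and adjusted p = 0.868 with an estimated correlation, exact permutation p = 0.34). The other was cholesterol synthesis (median 0.12 over 11 genes, adjusted p = 0.0317, and adjusted p = 0.483 with an estimated correlation, exact permutation p = 0.0836). In the first 17 of 22 genes were higher, with CCNB1 at 0.85 (SE 0.41), and in the second 9 of 11, with MVK at 0.47 (SE 0.15). Against the 3 artery-named controls the mean differences were 0.78 and 0.21. Cell cycle was lost without control animal 7 or FO animal 1 (highest adjusted p = 0.145), and cholesterol synthesis without 6 of the 20 animals in turn (highest adjusted p = 0.214). EDN1 was at 0.46, TBXAS1 at -0.52, PTGS1 at -0.98 and NOS3 at -0.02, and none passed.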

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

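Of the tests below, those of degraded RNA, of smooth muscle cells and of the label style for the smooth muscle pattern, those of the pairing, the slope test of the opposed shifts and the label style test of native cell cycle genes were chosen only after the result was seen, as was the exchange of arrays within pairs.

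Samples far from the rest of their group were sought in 192 groups of values, of which 15 had one where chance gives 9.6. Control animal 8 accounted for 5 of them, all on its native array: the smooth muscle level was 10.20 (next 8.66), ACTA2 was 13.49 (next 9.45), the interferon level was 8.62 (next 11.03), and the 3'/5' ratios were 3.39 for actin (next 2.11) and 1.66 for GAPDH (next 1.25). The regenerated array of control animal 6 had an actin ratio of 264 (next 6.89) and a GAPDH ratio of 1005 (next 1.48). For the regenerated array of FO animal 3 these ratios were 422 (next 3.86) and 59.9 (next 1.82), and its ribosomal protein level was 12.54 (next 12.997). The native array of FO animal 1 had an interferon level of 10.15 (next 11.66). The regenerated array of CHL animal 4 had an oxidative phosphorylation level of 11.10 (next 11.70). OLR1 was at 8.89 on the regenerated array of CHL animal 1 (next 5.47). NOS3 was at 8.04 on the native array of control animal 7 (next 9.70) and at 10.86 on the regenerated array of FO animal 1 (next 9.57).

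The change from native to regenerated cells differed between CHL and control animals for 5 lists by camera with the preset correlation: interferon response (median difference 1.13, adjusted p = 0.00017), inflammatory genes (0.80, adjusted p = 0.00636), smooth muscle (-0.81, adjusted p = 0.00017), cell cycle (-0.51, adjusted p = 0.00387) and oxidative phosphorylation (-0.16, adjusted p = 0.0288). Each had an adjusted p of 0.652 with an estimated correlation. Between FO and control animals it differed for cell cycle (-0.56, adjusted p = 4.85e-06, and 0.662 with an estimated correlation) and ribosomal proteins (-0.086, adjusted p = 0.0223, and 0.954 with an estimated correlation).

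The first pattern is the higher smooth muscle list in regenerated control cells, and degraded RNA on 1 regenerated array was argued against, since the mean shift over the other 7 pairs was 1.03 (SE 0.34, exact sign-flip p = 0.0312). This covers only the array above the limit. Below it, actin ratios rose in control animals 4 (1.39 to 4.48) and 5 (1.43 to 6.89), which had the largest shifts. In control animal 1 the ratio fell (1.48 to 1.33) with a shift of 0.99. Milder degradation was not tested and stays open. Smooth muscle cells in the regenerated cultures may be a source and stay open, since the correlation of the smooth muscle and endothelial shifts over 20 animals was -0.37 (permutation p = 0.105), which decides nothing, and ACTA2 was at a log2 level of 11.82 in regenerated control cells. The label style also stays open, with a mean shift of 0.65 in the 3 artery-named control pairs (SE 0.36, exact sign-flip p = 0.5, too few pairs to pass). Pairs whose 2 arrays are not of 1 animal stay open, with a mean shift of 0.68 over the 6 control pairs correlated above 0 (SE 0.21, exact sign-flip p = 0.0625), and a choice of pairs by that correlation is not independent of the shift. Regeneration and the artery of origin are biological explanations that the design names and that were not tested apart.

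The second pattern is that smooth muscle and interferon shifts were opposed across animals (r = -0.94). Simple dilution of endothelial cells by other cells would lower both endothelial and interferon genes alike, but the interferon slope was steeper than the endothelial one by -1.29 (SE 0.13, permutation p = 1e-05, the smallest possible), with slopes of -1.41 and -0.11. Degraded RNA of the 2 arrays above the limit was argued against by r = -0.95 over the other 18 animals, and pairs not of 1 animal by r = -0.87 over the 14 pairs whose 2 labels carry the same animal number (permutation p = 1e-05, the smallest possible, and 0.00017). Milder degradation below the limit was not tested here either. A state of the cultures that needs no regeneration may be a source, since the levels were also opposed on the 20 native arrays (r = -0.72, rho = -0.61, permutation p = 0.00055 and 0.00506). The relation on the native arrays met the limit set before the result was seen. This source stays open by checks that were not part of that rule. The relation fell to r = -0.43 (permutation p = 0.0722) without the 2 farthest arrays, was -0.90, -0.89 and -0.04 within control, CHL and FO animals and -0.70 with artery names, and so rests on few arrays.

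The third pattern is the higher cell cycle list in native CHL cells. The label style was argued against, since the difference was 1.08 against the 3 artery-named controls (SE 0.29, exact permutation p = 0.0119, the smallest possible). The 5 other controls, at 9.18, lay nearer to the CHL level of 9.48. A single control animal was argued against by the lowest difference with 1 left out, 0.45 of 0.59. That a high cholesterol diet raised division genes in native cells is a hypothesis, found and tested on the same animals, and chance splits are weighed next.

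Other splits of the samples were planned before the results were seen. For control pairs 4 of 100 drawn gave as many probe sets as the real split (52 real, highest other 2153). For FO pairs 1 of 32 did (7 real, highest other 0), the smallest share possible. For native CHL cells 2 of 100 did (2 real, highest other 122). Few splits reached these counts, but the shares were not adjusted over the 7 comparisons, so chance was not excluded as their sole source. In native CHL cells no probe set passed with any 1 CHL animal left out. The same held with artery-named animals alone and with the label style as a batch term. Chance was not excluded for CHL pairs either (2 of 32, 1 real, highest other 1). Where the real count was 0 every split gives as many, so the splits could not exclude chance whatever they gave: for the CHL difference (100 of 100, 0 real, highest other 22), for the FO difference (100 of 100, 0 real, highest other 115) and for native FO cells (100 of 100, 0 real, highest other 380). Splits that call many times the real count point to a structure of the samples. For control pairs it lies with animals 3 and 8: the count was 66 with the native and regenerated arrays of animal 3 exchanged, 2051 with those of animal 8 and at most 2 with those of any other control animal. Control animal 8 had the lowest smooth muscle shift of the control pairs (-0.03, the others from 0.16 to 2.60) and the highest interferon shift (0.30). The count of 2051 does not show that its arrays were exchanged, since the count was 2398 with this animal left out. Of 22 probe sets that moved one way in the other 19 pairs, 17 moved the same way in it as labelled and 5 the opposite way. An exchange would turn such probe sets, so for these 22 the values argue against it. The number opposite was 6 in control animal 7 and FO animal 4 and 7 in CHL animal 4 and FO animal 5. The 17 moved one way in all 20 pairs, so that number is the same for every pair. For numbers of lists chance was not excluded in any comparison: 54 of 100 splits for control pairs (3 real, highest other 8), 24 of 32 for CHL pairs (2 real, highest other 6), 9 of 32 for FO pairs (6 real, highest other 7), 16 of 100 for the CHL difference (5 real, highest other 8), 77 of 100 for the FO difference (2 real, highest other 7), 15 of 100 for native CHL cells (5 real, highest other 8) and 91 of 100 for native FO cells (2 real, highest other 7).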

How the results depend on the processing

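The fits without animals with degraded RNA, the fits without the 3 pairs whose arrays correlated below 0, the gene lists with 1 animal left out, the exact list tests and the mean over the diets were chosen only after seeing the data. No called gene turned direction: over the alternatives 95 values of called genes lost the threshold and the others kept it, and of called lists 106 kept it, 72 lost it and 1 turned. The turned value is the ribosomal median of the FO difference, 0.015 after quantile normalization (adjusted p = 0.94). The cause of the changes below was not tested, except that fewer animals enter where some are left out. The spread is shared by the diets in each fit, so leaving out a pair of 1 diet can change the counts of another. For control pairs (52 probe sets) the count was 20 with a pseudocount of 1, 156 with 64, 22 with the filter at the 50th percentile, 25 with array quality weights, 0 with artery-named animals alone (803 unadjusted), 8 with no replicate block, 1437 with the animal as a random block, 584 without FO pair 6, 16 without degraded RNA and 6 without the pairs below 0. For CHL pairs (1) it was 12 with weights, 8 with a random block and 3 without the pairs below 0. For FO pairs (7) it was 3 with a pseudocount of 1, 3 at the 50th percentile, 23 with weights, 2 with artery names alone, 2 with no replicate block, 14 with a random block, 2 without FO pair 6, 2 without degraded RNA and 2 without the pairs below 0. For the CHL difference (0) it was 1 with a random block. For native CHL cells (2) it was 4 after quantile normalization, 1 with a pseudocount of 64, 1 at the 50th percentile, 566 with weights, 0 with artery names alone (1427 unadjusted) and 0 with the label style as a batch term (1522 unadjusted). For native FO cells (0) it was 84 with weights. The methods' t-test gave, unadjusted and after Benjamini-Hochberg adjustment, 3320 and 0 for control, 1221 and 0 for CHL and 902 and 0 for FO pairs, 2205 and 0 for the CHL and 744 and 0 for the FO difference, 2695 and 1 for native CHL and 1314 and 0 for native FO cells. The other counts, 51, stayed within 1.5 times.

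With an estimated correlation, and by the exact tests after adjustment, 0 lists passed in each of the 7 comparisons (smallest exact adjusted p from 0.0585 to 0.374). The number of lists was 3 in FO pairs without the pairs below 0. For the FO difference it was 1 after quantile normalization, 1 with artery names alone and 0 without the pairs below 0. It was 2 for native CHL cells with artery names alone, and for native FO cells 1 with the mean over probe sets and 4 with artery names alone. The other 29 numbers of lists stayed within 1.5 times. Called lists lost under other settings include the oxidative phosphorylation CHL difference after quantile normalization (adjusted p = 0.0856) and with no replicate block (0.0624), and the ribosomal call in FO pairs after quantile normalization (0.838).

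With 1 animal left out, control pairs gave 9 to 2398 probe sets: 13, 15, 1449, 10, 9, 16, 83 and 2398 without control animals 1 to 8, 20 and 34 without CHL animals 2 and 6, and 31, 256, 33 and 584 without FO animals 2, 3, 4 and 6. CHL pairs gave 1 to 4 (4 without CHL animal 4, 2 without control animal 7), FO pairs 2 to 8 (2 without FO animal 1, 3 or 6, 3 without FO animal 5, and 4 without FO animal 4 or control animal 1 or 4), the differences 0 to 0, native CHL cells 0 to 232 (232 without control animal 8, 5 without control animal 7, 0 without control animal 2, 3 or 4 or any CHL animal) and native FO cells 0 to 16 (16 without FO animal 3, 3 without control animal 6, 1 without control animal 7). Lists numbered 2 to 4 in control, 1 to 3 in CHL (1 without CHL animal 4) and 2 to 7 in FO pairs (2 without FO animal 6), 3 to 5 for the CHL difference (3 without CHL animal 3), 1 to 4 for the FO difference (1 without control animal 5 or 7 or FO animal 3, 4 without FO animal 6), 2 to 6 in native CHL cells (2 without CHL animal 1 or 3, 3 without control animal 7) and 0 to 3 in native FO cells (0 without control animal 7, 1 without control animal 2 or 3 or FO animal 1). All 12 genes called in control pairs lost their call with artery-named animals alone, with no replicate block, without the pairs below 0 and by the adjusted t-test of the methods. Of 13 settings CALCB lost it in 4, ACTA2 and GPC4 in 9 and OLR1 in 10, ADAM17 in 4 of 12, and CALCB in FO pairs in 9 of 13. Over these settings and the fits without 1 animal the log2 change of OLR1 ran from -2.89 to -0.54, that of CALCB from -1.62 to -1.03, that of ACTA2 from 2.34 to 4.29 and that of GPC4 from 1.07 to 1.94. CALCB kept its call in control pairs without any 1 animal, ADAM17 lost it in 2, GPC4 and OLR1 in 12 and ACTA2 in 14 of 20 fits, and CALCB in FO pairs in 9.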

Other observations

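The mean regenerated effect over the 3 diets and the search for probe sets that moved one way in all pairs were chosen only after the results were seen.

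Over the 20 animals, regenerated cells had lower POSTN, OLR1, CRSP-2 and CALCB and higher GPC4, CXCL12 and PPARG. By limma 480 probe sets passed for the mean effect over the diets, 266 higher and 214 lower, with 54 named genes higher and 50 lower and 4206 probe sets at an unadjusted p under 0.05. POSTN, a secreted matrix protein, fell by 2.79 on the log2 scale (SE 0.42, adjusted p = 0.00114) in 18 of 20 pairs, and OLR1 fell by 2.26 (SE 0.33, adjusted p = 0.000825) in 18 of 20. CRSP-2, a peptide of the calcitonin family, fell by 2.36 (SE 0.32, adjusted p = 0.000405) and CALCB by 1.28 (SE 0.16, adjusted p = 0.000117), each in 20 of 20 pairs, and cross-hybridisation between these related genes was not tested. FST, which binds activins, fell by 1.33 (adjusted p = 0.00252), the growth factor AREG by 1.07 (adjusted p = 0.0126) and TNFSF10, a death ligand, by 1.28 (adjusted p = 0.0476).

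GPC4 rose by 1.61 (SE 0.23, adjusted p = 0.000825) in 20 of 20 pairs, CXCL12 by 1.499 (SE 0.31, adjusted p = 0.012) in 19 of 20 and PPARG by 1.24 (SE 0.18, adjusted p = 0.000873) in 18 of 20. The glutamate transporter SLC1A1 (1.67, adjusted p = 0.026), FAP (1.38, adjusted p = 0.0462), MMP7 (1.32, adjusted p = 0.0104), FABP4 (1.29, adjusted p = 0.0192) and STMN2, a tubulin-binding protein (1.27, adjusted p = 0.0431), also rose. STMN2 was at 1.78 in control, -0.17 in CHL and 2.20 in FO pairs and SLC1A1 at 2.40, 0.47 and 2.16, and no difference between the diets passed. The count was 613 after quantile normalization, 58 with no replicate block, 244 without the animals with degraded RNA, 117 without the 3 pairs whose arrays correlated below 0 and 24 with artery-named animals alone.

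In 20 of 20 pairs 17 probe sets moved one way, 6 higher and 11 lower, where 0.0343 were expected by chance. They include GPC4, the calcium channel TRPC1 (mean difference 0.54 ± 0.40, SD) and the prion protein gene PRNP (0.59 ± 0.47) among the higher, and CALCB, CRSP-2 and probe sets titled as a zinc finger protein (-1.68 ± 0.62) and ectonucleotide pyrophosphatase/phosphodiesterase 2 (-1.23 ± 1.06) in the authors' deposited table among the lower. In every pair native cells came from one artery and regenerated cells from the other, so the artery of origin and regeneration cannot be told apart for these 17 probe sets.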
